A study of Caenorhabditis elegans with 2 samples.

How the data were processed

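The data came from chromatin immunoprecipitation with sequencing (ChIP-seq) of a GFP-tagged transcription factor in whole Caenorhabditis elegans larvae of the L3 stage, pooled over both sexes. The strain was OP355, which carries the integrated transgene wgIs355 in an unc-119 mutant background. Per the labels there were 2 biological replicates of 1 kind of sample, so no comparison between groups of samples exists. The labels name different targets. The antibody and strain labels name mdl-1, while the free-text description names ZK337.2, which the annotation lists as klu-1. Both names were therefore examined, and the tagged protein is called the tagged factor.

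The values analysed were lists of called regions that the authors deposited for builds ce10 and ce11. Per the deposited file descriptions, each replicate list was made from the alignments of 1 replicate and a control alignment, and the pooled list from both replicates and the same control. The list of reproducible regions, thresholded by irreproducible discovery rate (IDR), was made from the pooled and both replicate lists. The aligner, the peak caller, its thresholds and the IDR cutoff are not given in the sources used here. Each region in the deposited lists has a signal value, treated here as a score of the peak caller with no stated scale, and used only to rank or describe regions within a list. A deposited column of −log10 q-values took a single value throughout the IDR list and was not used. Read depth is not given in the sources used here, so no value could be weighted by depth, and intervals cover counting error over regions or genes only. The replicate lists differed in length, with 15898 regions for replicate 1 and 30000 for replicate 2, and the pooled list also held 30000.

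The ce11 lists gave the main results. Sequence and annotation were those of assembly WBcel235, which is ce11, with Ensembl release 115 annotation of 19973 protein-coding genes on chromosomes I to V and X. Coordinates are 1-based. No coordinate was converted between builds. For the ce10 lists, only counts, shares of chromosomes and overlaps among ce10 lists were computed, with ce11 chromosome lengths standing in for those of ce10.

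Overlap between replicates was taken over the 1015 regions of highest signal in each replicate, the number in the IDR list, with an overlap of at least 1 bp. Chance was set by 1000 circular shifts within chromosomes, which can give no two-sided p below 0.002. A promoter window ran from 1000 bp upstream to 200 bp downstream of the annotated 5′ end of a protein-coding gene. Summits outside promoter windows were classed as exon, intron or intergenic in that order. Shares of chromosomes were tested with exact binomial tests, and gene lists with two-sided Fisher's exact tests against all other protein-coding genes. Sequence motifs were searched on both strands within 100 bp of a summit and in a window of the same size centred 500 bp to 1 side of it. The side was drawn with a fixed seed and switched where that window touched a listed region. A region with no free side was left out. Windows were compared with the exact McNemar (binomial) test. The same test was run over all 6-mers after merging reverse complements. Adjusted p-values are Benjamini-Hochberg values over the motifs, the 6-mers or the gene lists, with a threshold of 0.05. Intervals are exact Clopper-Pearson intervals at 95%. Correlations across regions used 100000 permutations and two-sided p-values, with a region missing from a replicate list entered at 0. Calculations were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

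The 27 gene lists, the 18 motifs, the tests of the main results and the rule for named genes were set before the data were examined. The calculations first departed from that plan in some details and were corrected to it when values were already known, and some tests in the closing section, named there, were chosen after the data were seen. The lists were the Myc/Mondo network, ribosomal proteins, translation factors, nucleolus and ribosome biogenesis, cell cycle and DNA replication, histones, cuticle collagens, hypodermis and molting, body wall muscle, intestine, pharynx, neurons, neuropeptides, germline, heat shock and chaperones, oxidative stress and detoxification, insulin and TOR pathway, insulin-like peptides, lipid metabolism, autophagy and lysosome, nuclear hormone receptors, basic helix-loop-helix genes, homeobox genes, proteasome, mitochondrial respiration, splicing and chemoreceptors. Genes were named when their promoter window held the summit of 1 of the 20 regions of highest IDR signal (the nearest 5′ end if several), or when they were among the 4 members of a list with the highest IDR signal. All members of the Myc/Mondo network, mdl-1, klu-1 and unc-119 were named regardless. Genes named in the report for other regions among those 20 (nhr-19, aakg-1, abts-4, hif-1 and egl-9) fall outside this rule and were chosen after their values were seen. A summit between divergent genes can count for both, and genes within operons can lack a promoter of their own.

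The procedures were tested on simulated data. With 50% of 1015 random regions shared, the overlap step returned 50.3%, and with none shared it returned 0.493%. With CACGTG placed in 10% of 1015 genomic windows, the 6-mer scan ranked it first and called 2 other 6-mers, and with 30% of windows it called 10 others. Those windows were drawn at random positions, with no built-in difference in GC content from their flanks. Summit windows did differ from flanks (45.9% against 35.1% GC), so these counts do not bound the false calls of the scan in the data. With 20% of a list's members hit, the gene-list test over 19973 genes called it in 98% of runs, with 4 false calls over 100 runs. The simulated lists did not overlap, and each was as large as the heat shock and chaperones list (60 members). Many lists tested here were smaller, down to 6 members, so that rate does not carry over to them, and a list that did not pass may lack power. Alternatives tried were ce10 lists, other overlap criteria and list lengths, other promoter and motif windows, control windows at genes without a region, other gene backgrounds, a stricter list of the 507 regions of higher signal, the top of the pooled list, and the top regions of a single replicate in place of the IDR list.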

Results

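Binding of a GFP-tagged transcription factor was mapped in L3 larvae by ChIP-seq in 2 biological replicates, whose read depth is not given in the sources used here. The IDR list held 1015 reproducible regions in build ce11, with a median width of 364 bp. Signal values in that list ran from 25.9 to 539, with a median of 39.4. There were 271 regions on chromosome X, 172 on III, 151 on V, 147 on IV, 143 on II and 131 on I. These correspond to 15.3 regions per Mb on X, 12.5 on III, 9.36 on II, 8.69 on I, 8.40 on IV and 7.22 on V. The 1015 regions were identical to the 1015 regions of highest signal in the pooled list, so that list adds no separate evidence.

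The replicates were compared first, to ask whether they called the same places. The same region upstream of mdl-1, which encodes a Mad-like basic helix-loop-helix protein, ranked 1 in both replicates. Regions in nhr-19, which encodes a nuclear hormone receptor, and upstream of epn-1, an epsin homologue, were within the 10 highest in each. Of the 1015 regions of highest signal in replicate 1, 570 (56.2%) overlapped 1 of the 1015 highest in replicate 2. Circular shifts gave 0.707% on average and 1.67% at most (permutation p = 0.002, two-sided, the smallest the shifts can give). Across IDR regions, signal in the replicates was correlated with Spearman's rho of 0.445 and Pearson's r of 0.809 (two-sided permutation p = 1e-05 for each, the smallest the permutations can give). Regions are not independent replicates, and these values describe 1 pair of libraries. The IDR list was itself made from both replicates, so the correlation is not an independent test of their agreement. Pearson's r also depends more than rho on the regions of highest signal. Of the 20 highest in the IDR list, 5 lay around mdl-1, and no correlation without them was computed. The IDR list leaned on replicate 2. Of its summits, 873 (86.01%, 95% interval 83.7 to 88.1) lay in the 1015 highest regions of replicate 2 and 650 (64.04%, 95% interval 61.0 to 67.0) in those of replicate 1. The whole list of replicate 1 lacked 98 of the IDR summits and that of replicate 2 lacked 4.

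The labels name different target genes, so signal was examined at both and at unc-119, the gene mutated in the strain background. The mdl-1 locus stood out and the klu-1 locus did not. Within 20 kb of the 5′ end of mdl-1 (WBGene00003163, ce11 chromosome X, 6742351 to 6743899, plus strand), the 5000 highest pooled regions included 29, with a summed signal of 3036. The median over 19973 protein-coding genes was 1 region and 25.8. The neighbouring gene R03E9.2, picked out after its value was seen, was the 1 gene with a higher sum, 3050 over 30 regions. At klu-1 (WBGene00013970, chromosome I, 14975419 to 14980596, plus strand) there was 1 region with a signal of 16.01, at the 41.1 percentile of genes. At unc-119 (WBGene00006843, chromosome III, 10902641 to 10908935, plus strand) there were 4 regions with a summed signal of 56.0, at the 73.9 percentile. Within 10 kb of klu-1, and within 20 kb of it in replicate 2, there were 0 of the 5000 highest regions. No IDR summit lay in the promoter window of klu-1 or of unc-119. These values describe the lists and do not settle which protein was tagged.

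The 4 IDR regions of highest signal lay in a 21.2 kb stretch around mdl-1 on chromosome X (ce11). It held 21 IDR summits, from 6729120 to 6750289, and only 1 further IDR summit lay within 100 kb of the mdl-1 5′ end. The highest region of the list (6742072 to 6742471, signal 539) had its summit 84 bp upstream of mdl-1, in sequence annotated as intergenic. Its CACGTG lay at 6742226 to 6742231 in the context GAGGCGCACGTGCATACA. The next (6742868 to 6743190, signal 365) had its summit in an intron of mdl-1, with TTCATCCACGTGCGTCTA around a CACGTG at 6742982 to 6742987. Rank 3 (6737582 to 6737997, signal 359) was intergenic and contained GGGATGCACGTGCGCCAG. Rank 4 (6750127 to 6750497, signal 353) lay in an intron of abts-4, an anion transporter gene, and contained TAGACCCACGTGTGGGTG. Rank 13 (6743842 to 6744167, signal 229.7) had its summit downstream of mdl-1, in sequence annotated as intergenic.

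**Figure D1:**
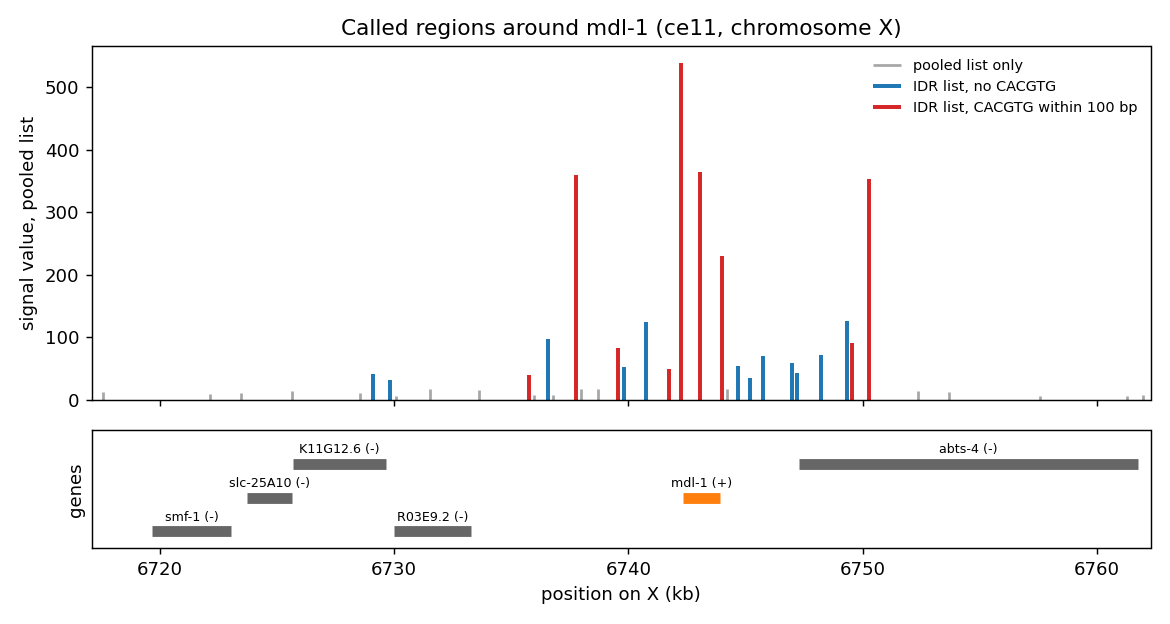
Signal value of called regions (vertical axis, pooled list, no stated scale) against position on chromosome X in kb (horizontal axis, ce11), with protein-coding genes drawn below. Lines are region summits, coloured by membership of the IDR list and presence of CACGTG within 100 bp, and the tallest, at 539, stands just upstream of mdl-1.

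Outside this locus, the highest regions lay in or near nhr-19, aakg-1 and epn-1, of which the first 2 were named after their values were seen. The region at chromosome II, 9603426 to 9603797 (signal 327), lay in an intron of nhr-19. That at chromosome III, 12583549 to 12583829 (signal 313), was intergenic, and the nearest 5′ end was that of aakg-1, which encodes a subunit of AMP-activated protein kinase. A region upstream of epn-1 (chromosome X, 14818793 to 14819182) also had a signal of 313, without a CACGTG within 100 bp of its summit. Intergenic regions nearest to hif-1, the hypoxia-inducible factor gene (chromosome V, 20778235 to 20778530, signal 176), and to egl-9, its prolyl hydroxylase (chromosome V, 10466614 to 10466857, signal 191), ranked 17 and 16, and these genes too were picked after the values were seen. The promoter windows of tasp-1 (chromosome III, 10759107 to 10759398, signal 224) and C36E6.2 (chromosome X, 17451504 to 17451721, signal 161) held the summits of ranks 14 and 20.

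Regions were then placed relative to genes. Summits lay in promoter windows more often than chance and rarely in exons outside them. The promoter share was 41.6% (422 of 1015, 95% interval 38.5 to 44.7), against 20.8% after circular shifts (permutation p = 0.002, two-sided, the smallest the shifts can give). Exons held 2.86% of summits against 22.9% by chance (permutation p = 0.002). Introns held 26.1% against 30.5% (permutation p = 0.014) and intergenic sequence 29.5% against 25.7% (permutation p = 0.024). The median distance from a summit to the nearest 5′ end was 1156 bp, and 64.7% of summits lay upstream of it. Within 200 bp of tRNA genes were 16 summits (1.58%, 95% interval 0.904 to 2.55), against 0.308% by chance (permutation p = 0.002, the smallest the shifts can give). Among the 507 regions of higher signal the share was 0.986% (permutation p = 0.044).

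Chromosome X and the central parts of autosomes were over-represented. X held 26.7% of regions (95% interval 24.0 to 29.5) but 17.7% of the genome (exact binomial p = 1.06e-12, two-sided). Of 744 autosomal summits, 350 (47.04%, 95% interval 43.4 to 50.7) lay in the middle 33.3% of the chromosome length (exact binomial p = 1.2e-14, two-sided). Of autosomal protein-coding genes, 38.1% had their 5′ end there. Against that share the excess of summits was smaller but remained (exact binomial p = 7.17e-07, two-sided).

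The E-box CACGTG, the binding site of Myc, Mad and Max proteins, was tested at summits because the strain label names mdl-1. Its share at summits was 11.5 times that beside them, and regions at mdl-1, in nhr-19 and near hif-1 had one. Of 1010 regions with a free flank, 299 (29.6%, 95% interval 26.8 to 32.5) had CACGTG within 100 bp of the summit and 26 (2.57%, 95% interval 1.69 to 3.75) had it in the flanking window. It was present only at the summit in 290 regions and only in the flank in 17 (exact McNemar p = 2.79e-65, two-sided). With the 1015 highest regions of replicate 1 alone the ratio was 6.15 (23.8% against 3.86%, exact McNemar p = 2.11e-40), and with control windows at the same offset at genes without a region it was 6.65. The ratio also moved with the window, to 25.11 in a shorter window of 50 bp each side (22.3% against 0.889%) and to 6.13 in a longer one (31.6% against 5.16%). The share was 46.5% in the 101 regions of highest signal (95% interval 36.5 to 56.7) and 24.5% in the 102 of lowest signal (95% interval 16.5 to 34.02). Among the 20 regions of highest signal, 13 had a CACGTG. Summit windows had a GC content of 45.9% against 35.1% in flanks. Among the 102 6-mers with the base composition of CACGTG, it ranked 1 by difference between summits and flanks.

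**Figure D2:**
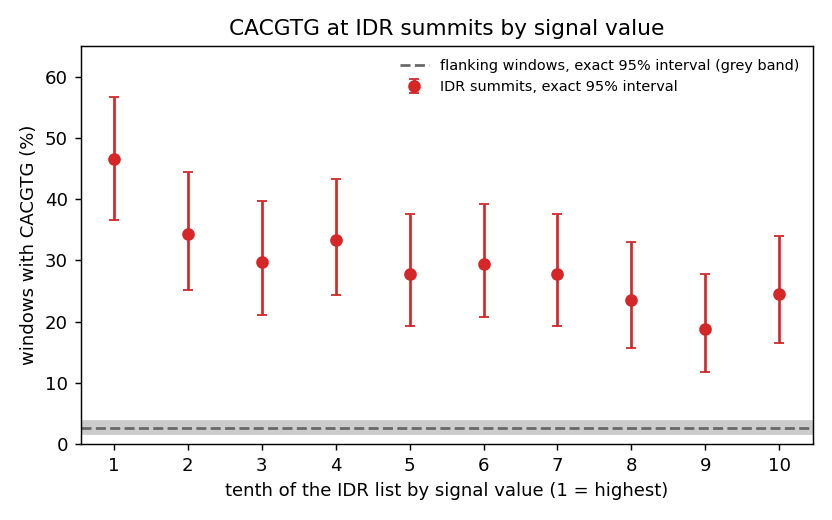
Share of summit windows with CACGTG (vertical axis, %) in 10 classes of the IDR list ordered by signal value (horizontal axis, 1 is highest). Points are shares with exact 95% intervals, and the dashed line and grey band give the flanking windows, at 2.57%, below every point.

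Other sequences were also more frequent at summits. GAGAGA was in 57.6% of summit windows and 10.2% of flanks (exact McNemar adjusted p = 2.72e-103). CTGCGTC was in 22.7% against 0.990% (exact McNemar adjusted p = 3.15e-55), and the variant site CACGCG in 15.7% against 1.78% (exact McNemar adjusted p = 4.22e-30). The Sp1- or KLF-like site GGCGGG was in 9.90% against 3.37% (exact McNemar adjusted p = 6.85e-09), and the extended E-box TCACGTGA in 2.18% against 0.198% (exact McNemar adjusted p = 7.18e-05). TCACGTGA contains CACGTG, so its call is not a separate one, and the test cannot tell the added bases from CACGTG itself. The bZIP site TGACGT was in 10.8% against 7.23% (exact McNemar adjusted p = 0.00948). Of the 18 motifs, 7 were more frequent at summits, CACGTG and the extended E-box that contains it among them. The 4 less frequent ones were the T-block, the heat shock element, CCAAT and the homeodomain site TAATTA. The GATA, forkhead, SKN-1, E2F, nuclear receptor, CAGCTG and CACCTG sites did not pass the test. CAGCTG did pass, as more frequent at summits, without replicate 1 and without replicate 2 (exact McNemar adjusted p = 0.00189 and 0.0446). Against windows at the same offset at genes without a region, which left 416 regions to compare, the extended E-box (1.92% against 1.20%) and the bZIP site (11.5% against 7.21%) lost the call (exact McNemar adjusted p = 0.697 and 0.0699). In that setting the E2F site passed as more frequent (0.0368) and the GATA site as less frequent (0.0268). With the 507 regions of higher signal, of which 504 could be compared, the bZIP site (10.3% against 6.75%) and CCAAT (26.6% against 31.3%) lost the call (exact McNemar adjusted p = 0.0876 and 0.153), and the GATA site passed as less frequent (0.0399). In the scan of 6-mers, 626 were more and 487 less frequent at summits, with no correction for the difference in GC content. CACGTG ranked 5 by exact McNemar p, after GAGAGA, AGAGAG, AGAGAC and CGTCTC. Those 6-mers overlap one another, CGTCTC being GAGACG on the other strand, so they need not be separate elements. Whether they and CTGCGTC form a single longer sequence was not tested. CACGTG ranked 13 without replicate 2, 9 with the 507 regions and 8 against windows at genes without a region.

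**Figure D3:**
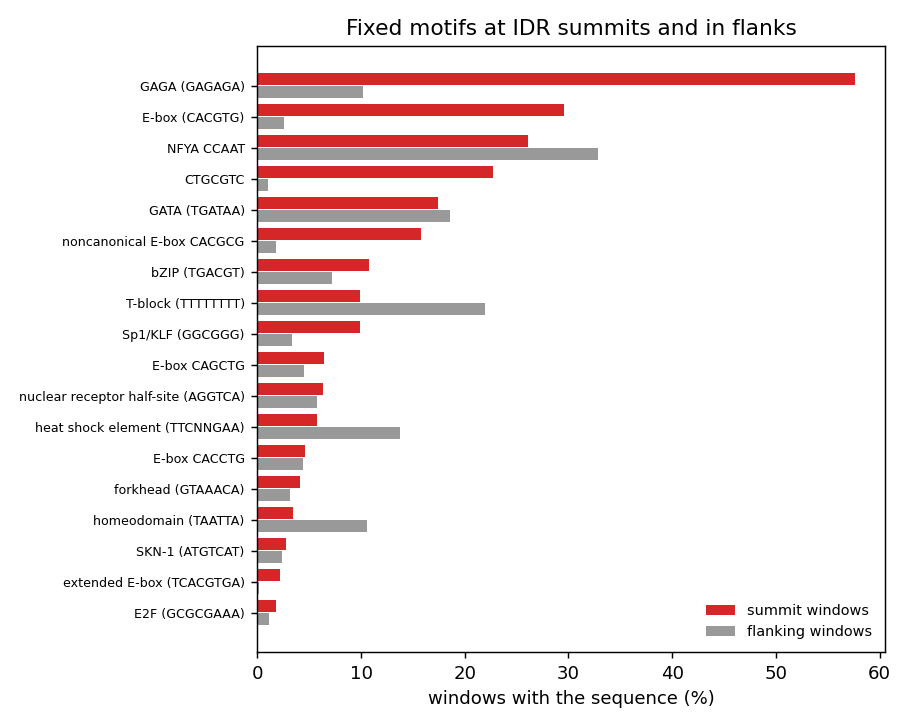
Share of windows with each of 18 fixed motifs (horizontal axis, %) at IDR summits (red bars) and in flanking windows (grey bars). GAGAGA is at 57.6% against 10.2% and CACGTG at 29.6% against 2.57%.

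Gene lists were compared with all other protein-coding genes, of which 504 of 19973 (2.52%) had an IDR summit in their promoter window. The lists that passed as enriched were ribosomal proteins, translation factors, heat shock and chaperones, autophagy and lysosome, mitochondrial respiration and nuclear hormone receptors. Ribosomal protein genes had the highest fold among them. Ribosomal protein genes had a summit in 15 of 80 cases (18.8%, 95% interval 10.9 to 29.0, 7.63-fold the share of other genes, Fisher's exact adjusted p = 1.73e-08), with the highest signals at rpl-15 (125), rpl-3 (103.5), rps-12 (77.3) and rpl-35 (65.2). Translation factor genes had one in 6 of 42 (5.72-fold, Fisher's exact adjusted p = 0.00513), among them eef-1A.2 (signal 125), iff-2 (98.6), eef-2 (39.3) and eef-1B.1 (37.7). The region at eef-1B.1 was not listed in replicate 1, and that at rpl-35 ranked 3162 there and 140 in replicate 2. Of 25 genes with the symbol prefix eif, counted after the data were seen, 0 had a summit. At the share of 2.52% over all genes, a 0 among so few says nothing about them.

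Heat shock and chaperone genes had summits in 7 of 60 cases (4.67-fold, Fisher's exact adjusted p = 0.00513), including hsp-3, cct-1, dnj-13 and hsp-60, with no region listed in replicate 1 at hsp-60. Autophagy and lysosome genes had them in 6 of 47 (5.11-fold, Fisher's exact adjusted p = 0.00604), including lgg-2 (signal 92.7), atg-9, epg-7 and lgg-1. Mitochondrial respiration genes had them in 5 of 42 (4.75-fold, Fisher's exact adjusted p = 0.0177), including cox-5A, cts-1, sdha-1 and cox-5B. Nuclear hormone receptor genes had them in 15 of 269 (2.25-fold, Fisher's exact adjusted p = 0.0177), led by nhr-1 (signal 89.7), nhr-48 (83.7), nhr-32 (82.0) and nhr-135 (61.7). Without replicate 1 the autophagy and respiration lists lost the call (3.54- and 3.96-fold, Fisher's exact adjusted p = 0.0897 and 0.0824), and without replicate 2 the translation factor and respiration lists (3.08- and 4.12-fold, 0.285 and 0.0727). Each of the 6 lists lost the call in some alternative, with adjusted p reaching 0.268 for autophagy and nuclear receptors and 1 for the other 4, in each case with only the regions that hold CACGTG. That alternative was chosen after the data were seen and leaves 134 genes with a summit. Folds in it were 1.87 for ribosomal, 6.42 for autophagy and 2.84 for nuclear receptor genes. They were 0 for translation factor, chaperone and respiration genes. With only the regions that lack CACGTG the autophagy and nuclear receptor lists also lost the call (4.58- and 2.01-fold, Fisher's exact adjusted p = 0.0515 and 0.142). A call lost with fewer genes therefore does not show a lower fold for these lists. Against genes with any pooled region folds were lower, at 3.81 for ribosomal, 3.67 for translation factor and 3.06 for chaperone genes, which kept the call. They were 2.86 for autophagy, 2.93 for respiration and 1.80 for nuclear receptor genes, which lost it (Fisher's exact adjusted p = 0.0904, 0.0973 and 0.0973). With the 507 regions of higher signal the ribosomal and autophagy lists kept the call. The others lost it, at 3.71-fold for translation factors and for respiration, 5.23-fold for chaperones and 2.34-fold for nuclear receptors (Fisher's exact adjusted p = 0.345, 0.345, 0.0508 and 0.130).

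Chemoreceptor genes, which act in sensory neurons, were depleted, with summits at 2 of 1276 (0.157%, Fisher's exact adjusted p = 9.53e-11), srh-17 and srh-16, of which the region at srh-16 was not listed in replicate 1. No summit lay at any of 173 cuticle collagen genes (upper 95% limit 2.11%, Fisher's exact adjusted p = 0.0824), 102 neuropeptide genes, 39 hypodermis and molting genes, 24 nucleolus genes or 17 pharynx genes, none of which passed the test. In the Myc/Mondo network only mdl-1 had a summit in its promoter window, and mml-1, mxl-1, mxl-2, mxl-3 and hlh-30 had none (1 of 6, Fisher's exact adjusted p = 0.384). The other 14 lists did not pass the test either, with adjusted p from 0.224 upward.

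Those lists had few members with a summit, here with their IDR signal. They included hlh-11 (149) among 31 basic helix-loop-helix genes, a list that leaves out mdl-1 and the other Myc/Mondo genes except hlh-30, cdc-48.1 (117) and lin-23 (75.9) among 49 cell cycle genes, ceh-38 (76.7) among 82 homeobox genes and cgh-1 (67.6) among 36 germline genes. Of 61 lipid metabolism genes, 3 had a summit, acs-2 (68.8), nhr-49 (50.2) and acl-1 (27.3), and this list passed the test in 1 of 11 alternatives, with a longer upstream window (Fisher's exact adjusted p = 0.00638). Of 18 insulin and TOR pathway genes, 2 did, the FOXO gene daf-16 (42.9) and rheb-1 (27.2). The 133 oxidative stress and detoxification genes included gst-42 (64.3) and gst-20 (42.3), and the 37 neuronal genes rgef-1 (37.8) and egl-21 (31.7). A single member had a summit among 39 insulin-like peptides (ins-39, 65.8), 72 histones (his-37, 41.1), 33 proteasome genes (rpn-11, 39.8), 32 body wall muscle genes (act-4, 37.9), 35 intestine genes (cpr-4, 27.7) and 31 splicing genes (snr-4, 27.6). The region at rpn-11 was not listed in replicate 1. Some other named regions were listed there at low ranks, 4601 for gst-42, 3393 for rheb-1, 3290 for act-4 and 3162 for rpl-35. Those at acl-1, dnj-13, cox-5A and cgh-1 ranked 2998, 2926, 2401 and 2134, and the remaining listed ones ranked higher.

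**Figure D4:**
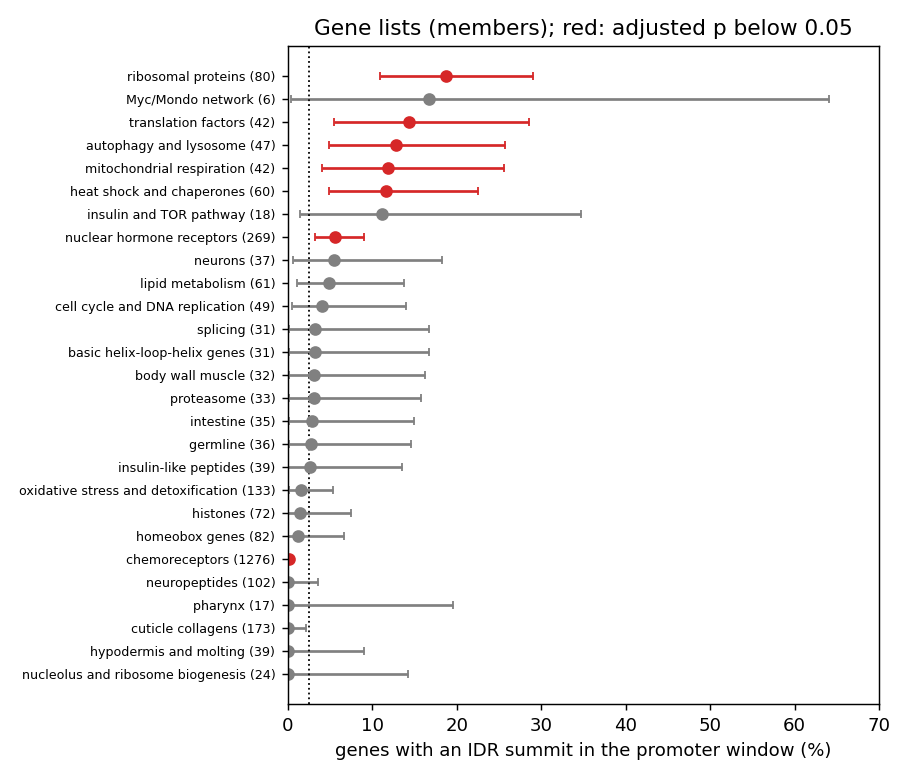
Share of genes with an IDR summit in the promoter window (horizontal axis, %) for 27 gene lists, with the number of members beside each name. Points are shares with exact 95% intervals, red marks an adjusted p below 0.05, and the dotted line is the share over all protein-coding genes, 2.52%.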

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

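Tests without the regions around mdl-1, with regions split by CACGTG, in classes of upstream distance, or of the X share against pooled regions were chosen after the data were seen. Of 85 alternative values for the main results, 68 kept their direction and side of the threshold, stayed within their interval or within 1.5 times the count. The top of the pooled list changed nothing because it is identical to the IDR list, so its values among the 68 were fixed in advance. A fall from 6 to 4 enriched gene lists counted as kept, being within 1.5 times. Calls of single motifs and single gene lists, some of which changed, are not among the 85. The list of 507 regions of higher signal is shorter by construction. With replicate lists of 2030 regions, 74.2% of IDR summits lay in that of replicate 1 and 98.03% in that of replicate 2, also by construction. The 6 enriched gene lists became 3 against genes with a pooled region only, 2 with the 507 regions, 0 with only regions that hold CACGTG, and 4 with only regions that lack it, where the ribosomal list had a fold of 9.67. With CACGTG regions only, 0 translation factor, 0 chaperone and 0 respiration genes had a summit, but only 134 genes in all did, so a 0 in lists of these sizes says nothing about them (Fisher's exact adjusted p = 1 for each), and the direct test of list members against other genes with a summit passed for no list (adjusted p from 0.96 upward). With a single replicate 4 lists were enriched in each case. The percentile of summed signal at mdl-1 was 100 within 10 kb, 100 within 5 kb and 100 in replicate 2. At klu-1 it was 0 within 10 kb, 0 within 5 kb, 48.5 in replicate 1 and 0 in replicate 2. A 0 there is a tie among genes with no region, since 10594, 6781 and 15241 of 19973 genes had more signal than klu-1 within 10 kb, within 5 kb and in replicate 2. At unc-119 it was 85.2 within 10 kb, 93.5 within 5 kb, 75.01 in replicate 1 and 67.6 in replicate 2, and the cause was not tested. Unknown read depth limits any reading of the difference between the replicate lists.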

Other observations

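The tests of motifs by presence of CACGTG, of E-box position and flanking bases, of E-box share by signal, of gene families by symbol, of gene lists by presence of CACGTG, and of the X share without mdl-1 or against pooled regions were chosen after the data were seen. Regions with a CACGTG differed in other sequences from those without. The GATA site TGATAA was in 27% of the 300 regions with CACGTG and 13.7% of the 715 without (Fisher's exact adjusted p = 1.44e-05 over 16 motifs). CACGCG went the other way, at 8.33% and 19.2% (Fisher's exact adjusted p = 6.96e-05). GAGAGA and CTGCGTC did not pass that test (Fisher's exact adjusted p = 0.147 and 0.140). E-boxes crowded towards summits, with 161 of 335 (48.06%) centred within 30 bp, against 30.6% for even spacing (exact binomial p = 2.75e-11). The base before CACGTG, read on either strand, was G in 22.1% of cases at summits and 13.2% elsewhere in the genome (Fisher's exact adjusted p = 2.54e-09), T in 27.3% and 23.5% (0.0288), and C in 28.8% and 38.8% (1.81e-07). Each site entered that test with both of its flanking bases, 670 at summits, treated as independent, which they need not be. Of 17729 genomic CACGTG sites, 335 (1.89%) lay within 100 bp of an IDR summit.

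Among 175 gene families sharing a symbol prefix, 4 were enriched at IDR summits, namely rpl (9 of 47 genes, Fisher's exact adjusted p = 0.000392), sec (5 of 19, 0.00629), rps (6 of 31, 0.00629) and lin (6 of 47, 0.049), the rpl and rps genes being those of the ribosomal protein list. A prefix groups genes by name only and need not mark related genes. The calls are also not separate, since lin-54 shares a summit with its divergent neighbour rpl-12, and sec-61.A shares one with rps-18. The nhr family, with the same counts as the nuclear hormone receptor list (15 of 269, 2.25-fold), did not pass among the 175 families (Fisher's exact adjusted p = 0.156). The ribosomal protein genes with a summit had CACGTG there in 1 of 15 cases against 27.2% of other genes with a summit, a difference that did not pass the test (Fisher's exact adjusted p = 0.96).

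Regions crowded around mdl-1, with 21 IDR summits within 20 kb of its 5′ end. An integrated transgene that carries the gene in extra copies could raise signal over its whole span. The prediction was that regions there would then hold CACGTG less often than elsewhere. They held it in 42.9% of cases (9 of 21, 95% interval 21.8 to 66.0), against 29.3% elsewhere, which lies within that interval, so extra copies are not excluded (one-sided Fisher's exact p = 0.94). Binding at E-boxes of its own gene predicts a CACGTG at the strongest mdl-1 summit, and 1 was present there. A CACGTG is also present at 29.3% of regions elsewhere and at 46.5% of the 101 IDR regions of highest signal. Extra copies could raise signal at sites that hold CACGTG too, so neither test can tell the explanations apart. Both explanations take mdl-1 as the tagged gene, which the values do not settle, and both stay open.

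The excess of regions on X was examined against technical sources. The regions around mdl-1 do not account for all of it, since 25.15% of the other regions were on X against 17.7% of the genome (exact binomial p = 3.88e-09). Nor does the relaxed pooled list as a whole, of which 19.8% outside the IDR list lay on X against 26.7% in the IDR list (two-sided Fisher's exact p = 1.55e-07). No biological explanation was tested.

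Most IDR regions lacked a CACGTG within 100 bp. Weak regions near the threshold do not account for this, since 65.7% of the 507 regions of higher signal lacked it (95% interval 61.4 to 69.8). The share with CACGTG was nonetheless higher in those 507 than in the other 508 (34.3% against 24.8%, two-sided Fisher's exact p = 0.000957). Signal from open promoters could contribute and cannot be told apart here, since regions without CACGTG lay in promoter windows in 43.1% of cases against 38% of those with it (two-sided Fisher's exact p = 0.143). No biological explanation was tested.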
